A study of Mus musculus with 2 samples.

How the data were processed

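Total RNA, with a stated size range above 200, was extracted from pooled E10.5 mouse forebrains by the mirVana method, per the labels' protocols, which also list a kit manual for very low RNA input. The labels number the 2 libraries as biological replicates 1 and 2, each from its own pooled biosample, and both formed the only group. Spike-ins were added per the labels. Whether priming used the poly(A) tail or random sequence is not given in the sources used here. The notes deposited with each sample give the assembly mm10 and genome annotation M4, the name of a GENCODE mouse release, and say that the tables derive from transcriptome alignments. The aligner, the quantification tool and their versions are not given in the sources used here; the column names are those of RSEM.

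The authors deposited a gene table and a transcript table per library. The expected counts are estimated reads per gene or transcript, not normalized, per the file headers, and need not be whole. The deposited TPM values are length-adjusted shares over all 69691 gene rows, spike-ins included, and the deposited posterior mean TPM is a second estimate of the same quantity. The FPKM values are read shares divided by transcript length, per the file headers. The transcript tables also give the percent of a gene's TPM in each transcript, per the file headers. Effective length was length minus 99 in 99.995% of the 41128 gene rows with an effective length above 0 (tolerance 0.05 bases), which inflates TPM of very short genes.

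Of the rows, 43346 carried Ensembl gene identifiers, 26248 a bare number and 97 were spike-in or phage controls. Symbols came from the gene name table for 42462 identifiers, and the 884 without a symbol held 0.252% and 0.260% of the gene counts of replicates 1 and 2. Gene coordinates are 1-based, from GENCODE M21 on GRCm38, the assembly also called mm10. The rows with a bare number entered no test.

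The named genes followed a rule fixed before the data were examined: up to 5 members of highest mean TPM in each of 30 lists and its members under 1 TPM in both libraries where these were fewer than 0.5 of the list, or up to 4 highest and up to 4 undetected members in lists with fewer than 0.5 detected; both genes of 24 fixed pairs; the 10 genes of highest mean TPM; up to 10 genes standing apart in each direction; genes with another leading transcript; and the 3 leading histone genes and spike-ins. Some genes that the rule names are not reported here. Genes named outside the rule were chosen after their values were seen. Lists cover forebrain, pallium, subpallium, dorsal midline, FGF and SHH, diencephalon, optic, midbrain, HOX, neuroepithelium, neurogenic commitment, neurons, Cajal-Retzius cells, synapse, glia, cell cycle, early embryo, surface ectoderm, placode and lens, mesenchyme, endothelium, pericytes, erythroid cells, macrophages, immediate early genes, p53 stress, hypoxia and glycolysis, structural RNAs, sex-linked and imprinted genes. Some genes are in more than a single list, such as Otx2, Tbr1 and Eomes.

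Levels were summarised as medians of log2(TPM + 0.1) per library, and list contrasts and gene pairs as differences within a library. A list's percentile was taken among 10000 random lists of its size. Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave TMM factors and the common dispersion with an intercept only, over genes with 10 counts or more in each library. Ratios between libraries used unrounded expected counts plus 0.5 over TMM-scaled library sizes. Genes with a mean count of 50 or more were called apart at a ratio over 5 spreads (1.4826 times the median absolute deviation in 40 bins of mean count) and over 1 on the log2 scale. List shifts used members with a mean count of 10 or more and random lists matched in 20 bins. Intervals of ratios are 95% exact binomial intervals of the pair of counts, and a count of 0 was set at a floor of 3 counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.

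The steps were tested on simulated data with the real means and library sizes for the comparison of replicate 2 with replicate 1. Of 200 changed genes, 100% of those changed 3-fold and 100% of those changed 8-fold were called, and none of 13664 unchanged genes was, in a step on 13864 genes. The changed genes had a mean count of 100 or more, and all genes shared a single dispersion. The real median spread was 0.361 on the log2 scale at mean counts of 50 to 200, where a 3-fold change can fall under 5 spreads. This recovery therefore does not extend to such genes. A shift of 0.2 on the log2 scale was found in 94 of 100 lists of 12 genes, and 5 of 100 unshifted lists fell outside the 95% range. The simulated genes varied independently of each other, so these list rates do not extend to real lists whose members vary together. The simulated coefficient of variation of 0.0707 was returned as 0.0705 over 16648 unchanged genes, and as 0.151 with the 200 changed genes included, so strongly changed genes raise this estimate.

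Alternatives fixed beforehand covered the TPM minimum, the estimate used (posterior mean TPM, FPKM, expected counts as CPM without division by length), the pseudocount, leaving out a library, DESeq2 1.42.0 size factors, spike-in scaling, TPM ratios, count minimums and the number of spreads. Alternatives added after the data were seen were rescaled TPM, whole counts only, and removal of a length and GC trend. The TPM credibility bounds and the posterior columns other than the posterior mean TPM are not used here. Library totals were 43021202 and 39215064 expected counts, and the median spread of the ratio between libraries was 0.361 on the log2 scale at mean counts of 50 to 200 and 0.0828 over 1000. The strand of counting is not given in the sources used here, so reads of overlapping antisense genes may be mixed.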

Results

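Total RNA from mouse embryonic forebrain at 10.5 days of development was sequenced as 2 libraries of a single group, each made from 10 ng of RNA. At this stage the forebrain is a thin-walled tube of dividing progenitors in which the first neurons appear. Replicate 1 came from a pool of 69 embryos and replicate 2 from a separate pool of 51 embryos of the same strain, B6NCrl, with both sexes in each pool. The gene tables held 43021202 expected counts in replicate 1 and 39215064 in replicate 2, of which 41537304 and 38012457 lay in annotated genes. The labels give no second tissue, stage or treatment, so the comparisons below are between groups of genes within a library and between the 2 pools. With 2 libraries no exact two-sided sign flip test can go below p = 0.5, so none is given. Values are the mean ± SD of the 2 libraries (n = 2) unless each library is named, and intervals and floors cover counting error only.

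At 1 TPM (a length-adjusted share of all transcripts) or more in both libraries, 14032 of 43346 annotated genes were detected. Of the 21474 protein-coding genes among them 12315 were detected. Of the 391 genes in 30 lists fixed before the data were examined, 306 passed the same limit.

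Genes that mark successive regions of the neural tube were compared within each library. Of 12 forebrain transcription factors 11 were detected in both libraries, led by Lhx2 at 95 ± 4.69 TPM, Nr2e1 at 71.7 ± 4.41, Otx2 at 52.4 ± 5.12, Otx1 at 36.2 ± 3.92 and Fezf1 at 32.1 ± 2.14. The median of that list lay at percentile 79.6 among random lists of its size, so the list as a whole was not unusually high. HOX genes, which mark hindbrain and spinal cord, gave almost no signal: none of the 22 genes in that list reached 1 TPM, and the highest mean was 0.10 TPM, for Egr2, followed by Hoxa7, Hoxd3 and Hoxb1 at 0.075, 0.07 and 0.03. The 21 HOX genes together drew 14 counts in replicate 1 and 10 in replicate 2, and 11 of them, among them Hoxa3 and Hoxa4, had no count in either library. A count of 0 allowed at most 3 counts, which was 0.0439 to 0.164 TPM depending on the gene's length. Hoxa2 had 1 count in each library.

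Midbrain and isthmus genes were mostly low. Of 11 such genes 5 were detected in both libraries, led by Pax3 at 10.7 ± 0.431 TPM, Nr4a2 at 6.44 ± 0.184, Pax7 at 1.95 ± 0.0778 and Pou4f1 at 1.31 ± 0.0849, while En1, En2, Pax5 and Pax8 stayed under 1 TPM in both. The median forebrain factor lay above the median midbrain gene by 4.91 ± 0.82 on the log2 scale, a 30-fold difference larger than the spread between libraries, and by 3.82 with a pseudocount of 1 and 3.78 over expressed members only. The gap to the HOX list was 7.86 ± 0.0034 on the log2 scale, but its size was set by the pseudocount, since the median HOX gene was at 0: it was 4.60 with a pseudocount of 1 and 11.18 with 0.01.

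Genes of both the dorsal and the ventral telencephalon were detected, the dorsal at higher levels. All 12 pallial genes were detected, with Pax6 at 66.4 ± 2.08 TPM, Nr2f1 at 53.7 ± 0.997, Gli3 at 51.9 ± 1.43, Emx2 at 39.2 ± 2.16 and Tfap2c at 34.6 ± 3.22. Of 12 subpallial genes 11 were detected, with Dlx1 at 27.8 ± 0.424 TPM, Dlx5 at 15.3 ± 0.474, Dlx2 at 14.2 ± 1.5 and Nkx2-1 at 11.2 ± 1.40, and only Dlx6 stayed under 1 TPM in both libraries (0.885 ± 0.120). The pallial median exceeded the subpallial median 2.52-fold (log2 1.33 ± 0.41).

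Genes listed for the forebrain signalling centres were detected, although RNA of whole pools does not show which cells expressed them. Of 15 dorsal midline and hem genes 13 were detected, led by Msx1 at 156.6 ± 10.7 TPM, Wnt7b at 104.7 ± 4.82, Rspo3 at 45.2 ± 5.23, Rspo1 at 36.9 ± 3.85 and Wnt8b at 35.9 ± 4.98, while Wnt2b (0.525 ± 0.0354) and the choroid plexus carrier Ttr (0.365 ± 0.219) were not. All 13 FGF and SHH genes were detected, among them Dusp6 at 87.1 ± 9.19 TPM, Fgf15 at 51.0 ± 9.22, Etv5 at 34.2 ± 6.67, Fgf8 at 28.1 ± 2.78 and Fgf17 at 25.8 ± 10.4. Diencephalic and hypothalamic genes were lower as a list, with a median of 2.46 ± 0.544 TPM and 11 of 15 detected. Tcf7l2, at 83.7 ± 4.43 TPM, stood far above Dbx1 at 12.5 ± 0.573, Irx3 at 10.8 ± 0.163, Lhx9 at 5.91 ± 2.03 and Foxd1 at 5.04 ± 0.311, while Irx1, Sim1 and Nkx2-4 were under 1 TPM in both libraries. Of 13 optic genes 9 were detected, with Otx2, a member of both lists, ahead of the melanosome protein gene Pmel (13.3 ± 10.6 TPM), Rax (6.63 ± 4.47), Dct (5.51 ± 1.52) and Six6 (4.78 ± 2.93). Vax1, Pax2 and Tbx5 were under 1 TPM in both libraries.

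**Figure D1:**
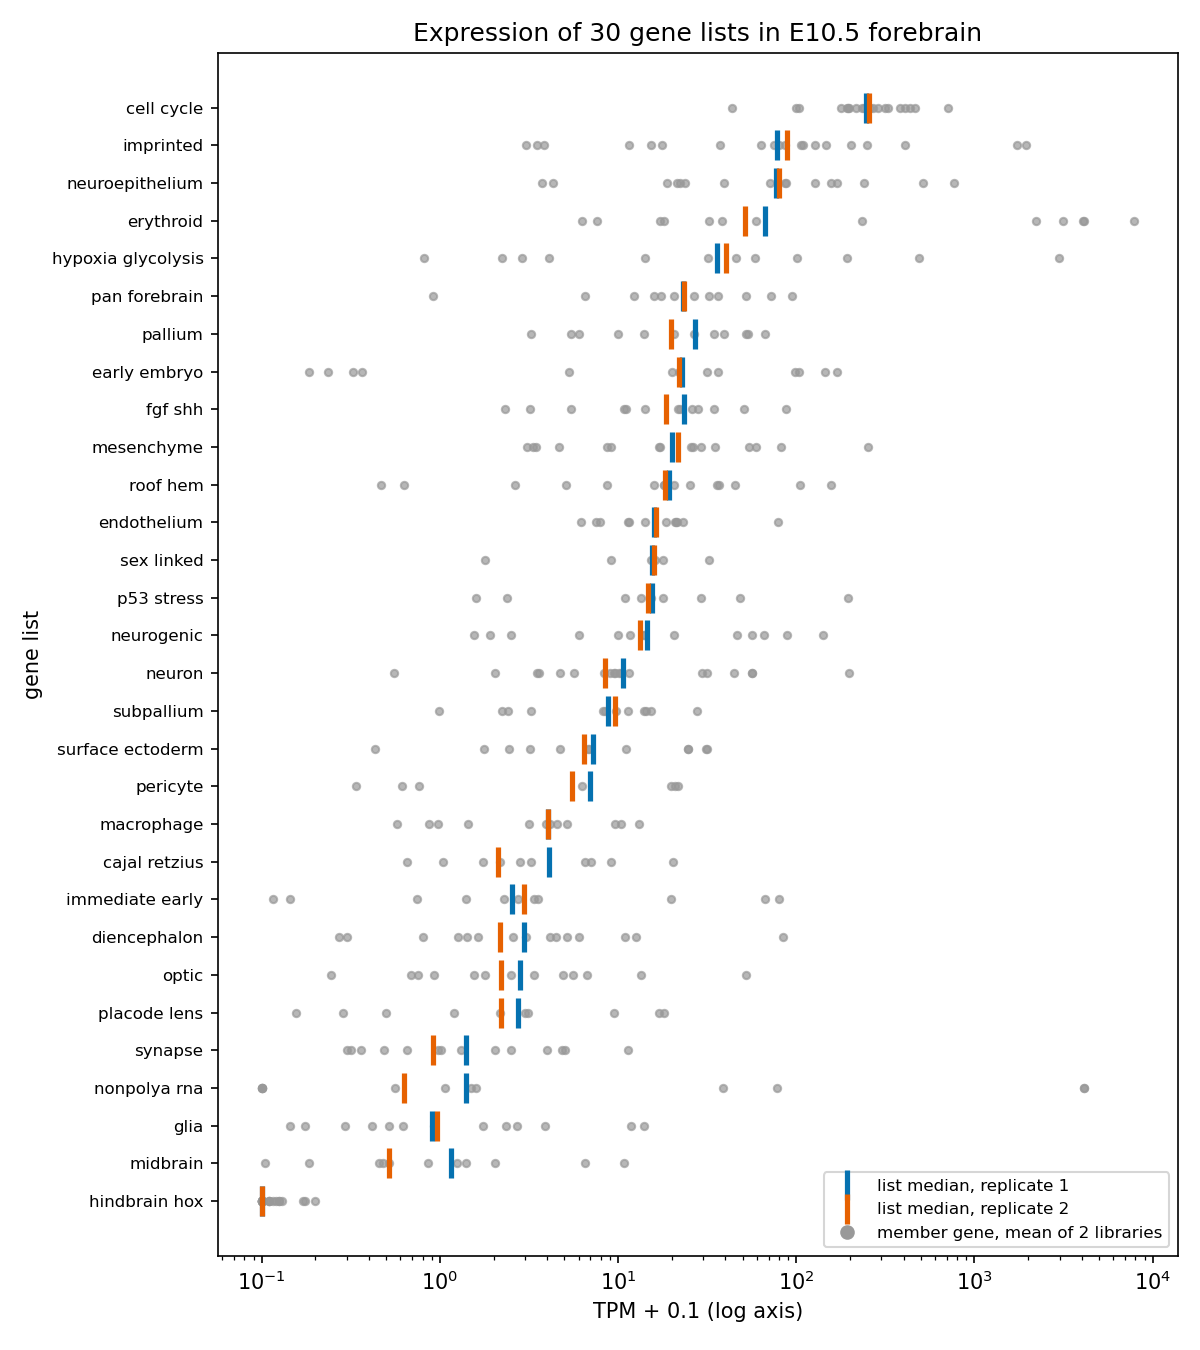
Expression of the 30 gene lists, with TPM + 0.1 on a log axis. Grey points are single genes (mean of the 2 libraries), blue and orange bars are each list's median in replicate 1 and replicate 2; the cell cycle list is highest, with a median of 250.6 TPM, and the HOX list lies at the floor set by the pseudocount.

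Cell cycle and neuroepithelial genes were among the most abundant lists. All 20 DNA replication and mitosis genes were detected, with a list median of 250.6 ± 5.68 TPM. The ribonucleotide reductase subunit Rrm2 led at 706.8 ± 0.629 TPM, followed by Cdk1 at 461.6 ± 6.34, Ccnb1 at 433.2 ± 20.4, Pcna at 405.0 ± 10.3 and Mcm7 at 379.7 ± 0.488. All 16 neuroepithelial genes were detected (median 79.0 ± 2.5 TPM), with the intermediate filament gene Vim at 765.4 ± 4.26 TPM, Hmgb2 at 515.0 ± 42.4, Hes5 at 240.6 ± 12.3, Cdh2 at 168.9 ± 0.332 and Fabp7 at 157.0 ± 52.6. Of 13 pluripotency and early embryonic genes 9 were detected, with Igf2bp1 at 168.8 ± 0.615 TPM, Igf2bp2 at 144.7 ± 12.1, Igf2bp3 at 103.0 ± 6.96, Hmga2 at 98.6 ± 1.53 and Lin28b at 36.1 ± 2.98, and Pou5f1, Nanog, Dppa5a and Utf1 were under 1 TPM in both libraries. Among 10000 random lists of the same size drawn from 15032 expressed or listed genes, the cell cycle median was at percentile 100 and the neuroepithelial median at 99.99.

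Genes of committed and differentiating neurons were detected at lower levels. All 14 genes of neurogenic commitment were detected (median 13.9 ± 0.944 TPM), with Hes6 at 141.5 ± 11.9 TPM, Gadd45g at 89.0 ± 3.49, Mfng at 65.8 ± 7.17, Btg2 at 56.6 ± 2.09 and Dll1 at 46.5 ± 2.04. Of 19 neuronal genes 18 were detected (median 9.41 ± 1.55 TPM), led by the neuronal tubulin gene Tubb3 at 198.0 ± 32.4 TPM, Map2 at 56.4 ± 8.11, Stmn3 at 56.2 ± 11.5, Elavl4 at 44.8 ± 6.80 and Gap43 at 31.4 ± 2.75, with Myt1l alone under 1 TPM in both (0.455 ± 0.219). Of 10 genes of Cajal-Retzius and other first-born neurons 8 were detected, with Lhx5 at 20.2 ± 2.02 TPM, Calb2 at 9.05 ± 2.40, Ebf1 at 6.99 ± 0.177, Ebf2 at 6.46 ± 1.77 and Tbr1 at 3.15 ± 1.59, and Ebf3 was under 1 TPM. Synaptic genes were lower, with 6 of 14 detected and a median of 1.07 ± 0.350 TPM: Dlg4 reached 11.2 ± 0.573 TPM, Gad2 4.92 ± 1.28, Camk2a 4.75 ± 0.679 and Slc17a6 3.87 ± 1.70, while Grin2a, Gria1 and Slc17a7 were under 1 TPM in both. Of 13 glial genes 6 were detected (median 0.830 ± 0.0424 TPM), among them Cnp at 13.9 ± 1.39 TPM, Mbp at 11.7 ± 0.389 and Aldoc at 2.61 ± 0.389, and Gfap, Aqp4, S100b and Sox10 were under 1 TPM in both.

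Within each library the median neuroepithelial gene lay above the median neuronal gene, and that above the synaptic and glial ones. The neuroepithelial median exceeded the neuronal median 8.31-fold (log2 3.06 ± 0.27), and the neuronal median exceeded the synaptic median 8.36-fold (3.06 ± 0.19) and the glial median 10.2-fold (3.35 ± 0.30). Genes of neurogenic commitment lay 1.47-fold above neuronal genes (0.55 ± 0.14), an order that turned when expected counts as CPM, without division by length, were used (-0.0697). Over head mesenchyme the neuroepithelial median was 3.77-fold higher (1.92 ± 0.03). Each of these 5 differences was larger than 1 SD between the libraries. Over expressed members only, the neuronal median exceeded the synaptic by 1.68 and the glial by 1.58 on the log2 scale, and with means in place of medians the neuroepithelial list exceeded the neuronal by 2.43.

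Markers of cell types outside the neural tube were detected too. All 16 mesenchyme and cranial neural crest genes were detected (median 21 ± 1.03 TPM), with Col3a1 at 250.9 TPM in both libraries, Col1a2 at 82.2 ± 1.87, Alx1 at 59.2 ± 5.61 and Col1a1 at 54.2 ± 1.53. All 12 endothelial genes were detected (median 16.2 ± 0.240 TPM), with Egfl7 at 79.3 ± 4.40 TPM, Esam at 23.0 ± 0.198, Kdr at 21.2 ± 1.10, Eng at 20.9 ± 0.0566 and Cldn5 at 20.8 ± 1.22. All 13 erythroid genes were detected, and globins, embryonic and adult, were among the most abundant transcripts: Hbb-y reached 7845 ± 1698 TPM, Hba-a2 4105 ± 1001, Hbb-bh1 4046 ± 774.6, Hba-x 3137 ± 696.5 and Hba-a1 2219 ± 519.2. Surface epithelium was detected through 11 of 12 genes (median 6.72 ± 0.544 TPM), with Krt8 at 31.6 ± 1.73 TPM, Krt18 at 31.2 ± 1.85, Cldn6 at 24.7 ± 2.53, Epcam at 24.6 ± 2.72 and Perp at 11.0 ± 0.792, and with Krt5 under 1 TPM. Pericyte genes (4 of 7 detected) were led by Pdgfrb at 21.5 ± 0.870 TPM, Vtn at 20.7 ± 0.651, Notch3 at 19.8 ± 0.304 and Acta2 at 6.14 ± 1.00, while Rgs5, Kcnj8 and Abcc9 were under 1 TPM. Macrophage genes (9 of 12) were led by C1qb at 13.0 ± 0.325 TPM, Fcer1g at 10.2 ± 0.0919, Tyrobp at 9.53 ± 1.04, C1qc at 5.08 ± 1.10 and Csf1r at 4.46 ± 0.148, with Ptprc and P2ry12 under 1 TPM. Placode and lens genes (6 of 10) included Eya2 at 18.0 ± 3.83 TPM, Eya1 at 16.9 ± 1.68, Dlx3 at 3.03 ± 0.0778 and Prox1 at 2.89 ± 0.431, with Cryaa, Cryba1 and Pitx3 under 1 TPM. All 6 sex-linked genes were detected, with Eif2s3y at 32.3 ± 6.96 TPM, Ddx3y at 17.8 ± 1.69, Uty at 16.1 ± 0.184, Kdm5d at 15.1 ± 0.566 and Xist at 9.01 ± 1.32, in pools of both sexes.

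Imprinted genes formed the second most abundant list, with all 20 detected and a median of 83.1 ± 7.86 TPM (percentile 100 among random lists). Mest reached 1957 ± 34.0 TPM, Nnat 1733 ± 151.1, Grb10 406.1 ± 11.1, Meg3 248.6 ± 1.47 and Dlk1 202.0 ± 46.0. Hypoxia and glycolysis genes (11 of 12 detected, median 38.8 ± 3.39 TPM) included Ldha at 2983 ± 156.5 TPM, Pgk1 at 487.3 ± 8.51, Slc2a1 at 192.6 ± 12.9, Bnip3 at 101.2 ± 10.8 and Slc2a3 at 58.7 ± 2.48, with Car9 under 1 TPM. Immediate early genes were modest (7 of 11, median 2.66 ± 0.297 TPM): Ier2 was at 80 ± 2.83 TPM, Jun at 66.8 ± 5.61, Dusp1 at 19.7 ± 1.34, Nr4a1 at 3.44 ± 0.573 and Junb at 3.27 ± 0.163, and Fos, Fosb and Hspa1b were under 1 TPM. All 10 p53 and stress response targets were detected (median 15.1 ± 0.523 TPM), led by Bax at 195.1 ± 3.79 TPM, Mdm2 at 47.9 ± 2.91, Ccng1 at 29.0 ± 2.04, Phlda3 at 17.7 ± 0.856 and Cdkn1a at 15.2 ± 2.55. Of 12 structural RNAs without a poly(A) tail 5 were detected, among them Rn7s1 and Rn7s2 at 4099 TPM each (SD 585.5 and 584.6), Rn7sk at 77.8 ± 6.36 and Rpph1 at 38.5 ± 5.98, and Rny3, Terc, Rprl1 and Rprl2 were under 1 TPM. Rn7s1 and Rn7s2 are near-identical copies, so their split is uncertain.

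Ratios of paired genes within a library compared early with late forms of chromatin, splicing and signalling proteins and anterior with posterior genes. The first gene of the pair was higher in both libraries in 17 of 24 pairs. Progenitor forms exceeded neuronal or mature forms for Actl6a over Actl6b (90.6-fold, log2 6.50 ± 1.02), Ss18 over Ss18l1 (15.8-fold), Ptbp1 over Ptbp2 (2.29-fold), Top2a over Top2b (4.56-fold), Ezh2 over Ezh1 (17.9-fold) and the chloride importer Slc12a2 over the exporter Slc12a5 (8.40-fold). The BAF subunit pair Phf10 and Dpf1 went the other way, with the neuronal form Dpf1 1.36-fold higher. Dnmt3a exceeded Dnmt3b 4.53-fold, Lin28b exceeded Lin28a 1.80-fold, Hmga1 exceeded Hmga2 7.66-fold and Tubb3 exceeded Sox2 9.24-fold. Regional pairs favoured anterior and dorsal genes: Otx2 over Gbx2 (41.8-fold), Pax6 over Nkx2-1 (5.91-fold) and Emx2 over Gsx2 (4.70-fold). Cdh2 exceeded Cdh1 25.2-fold, Slc17a6 exceeded Slc17a7 3.92-fold, Hbb-y exceeded the adult globin gene Hbb-bt 34.3-fold and Hba-x exceeded Hba-a1 1.42-fold. The near-identical copy of Hba-a1, Hba-a2 (4105 ± 1001 TPM), itself lay above Hba-x. The last pair therefore does not show embryonic alpha globin above adult. Ccnd1 and Ccnd2 were nearly level (-0.02 ± 0.01 on the log2 scale), as were Nr2f1 and Nr2f2 (0.18 ± 0.01) and Hk2 and Hk1 (0.33 ± 0.06), and the last 2 orders turned without division by length. Grin2b against Grin2a differed by less than the spread between libraries (-1.02 ± 1.28), with 14 and 2 counts of Grin2b. Reads of the globin genes can be split between near-identical copies, so their ratios are uncertain.

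The 10 genes of highest mean TPM outside the mitochondrial genome and the spike-ins were Hbb-y, Hist1h2ap (5929 ± 109.8 TPM), Actb (5258 ± 111.4), Ppia (5152 ± 70.6), Gm22133 (4657 ± 34.8), Ftl1 (4424 ± 74.1), Gm10123 (4399 ± 6.60), Gm28437 (4276 ± 375.1), Hba-a2 and Rn7s1. Gm22133 rested on 1282 and 1168 counts, since its effective length was 10 bases. It lies within Ftl1 on the same strand, so its reads can be those of Ftl1. The other unnamed gene models can share reads with near-identical copies. How the RNA was primed is not given in the sources used here, so the shares of RNAs without a poly(A) tail describe the libraries and not the tissue. Replication-dependent histone transcripts, most of which lack that tail, took 0.720% ± 0.0088 of TPM, with Hist1h4d at 342.5 ± 11.6 and Hist1h2ae at 188.9 ± 10.8 TPM after Hist1h2ap. Protein-coding genes took 84.4% ± 0.610 of TPM, ribosomal protein genes 6.58% ± 0.105, mitochondrial genes 1.77% ± 0.121, haemoglobins 2.16% ± 0.477 and the 7SL RNA copies 0.820% ± 0.117. The 353 rows annotated as nuclear ribosomal RNA took 0.00694% ± 0.0023. That share covers annotated rows only and does not measure all ribosomal RNA in the libraries. Long noncoding classes took 1.5% ± 0.0199 and pseudogenes 4.64% ± 0.103. Spike-ins took 7.42% ± 0.576 of TPM, and the 3 most abundant of them reached 25343 ± 2159, 10435 ± 709.6 and 9804 ± 761.1 TPM.

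Transcript tables were compared for 104 genes of the region and state lists with at least 10 TPM in both libraries. For the 75 genes with several annotated transcripts, the most abundant transcript carried a median 82.5% ± 1.14 of the gene's TPM, and in 31 genes it carried more than 90%. The same transcript was the most abundant in both libraries in all but 1 gene. That gene was Nes (GRCm38 chromosome 3, 87971078 to 87980451, plus strand), which encodes the progenitor intermediate filament nestin and has 3 annotated transcripts: ENSMUST00000160694.1 led in replicate 1 with 49.0% and held 39.2% in replicate 2, where ENSMUST00000090973.7 led with 57.2%. The latter held 48.7% in replicate 1, so the leading pair was nearly level there. These shares are estimates from reads that transcripts of a gene have in common.

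The 2 libraries were close but distinct. Across 15069 genes detected in either library, the correlation of log2(TPM + 0.1) across genes was 0.961 (Pearson) and 0.989 (Spearman); genes are not independent replicates. The biological coefficient of variation over 16637 genes was 6.59%, and 81 of 13842 genes with a mean count of 50 or more differed by over 2-fold. Over 11537 genes with whole counts, the chi-square of the counts was 6.70 times its degrees of freedom, which shows only that the tables do not hold a single library under both names.

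**Figure D2:**
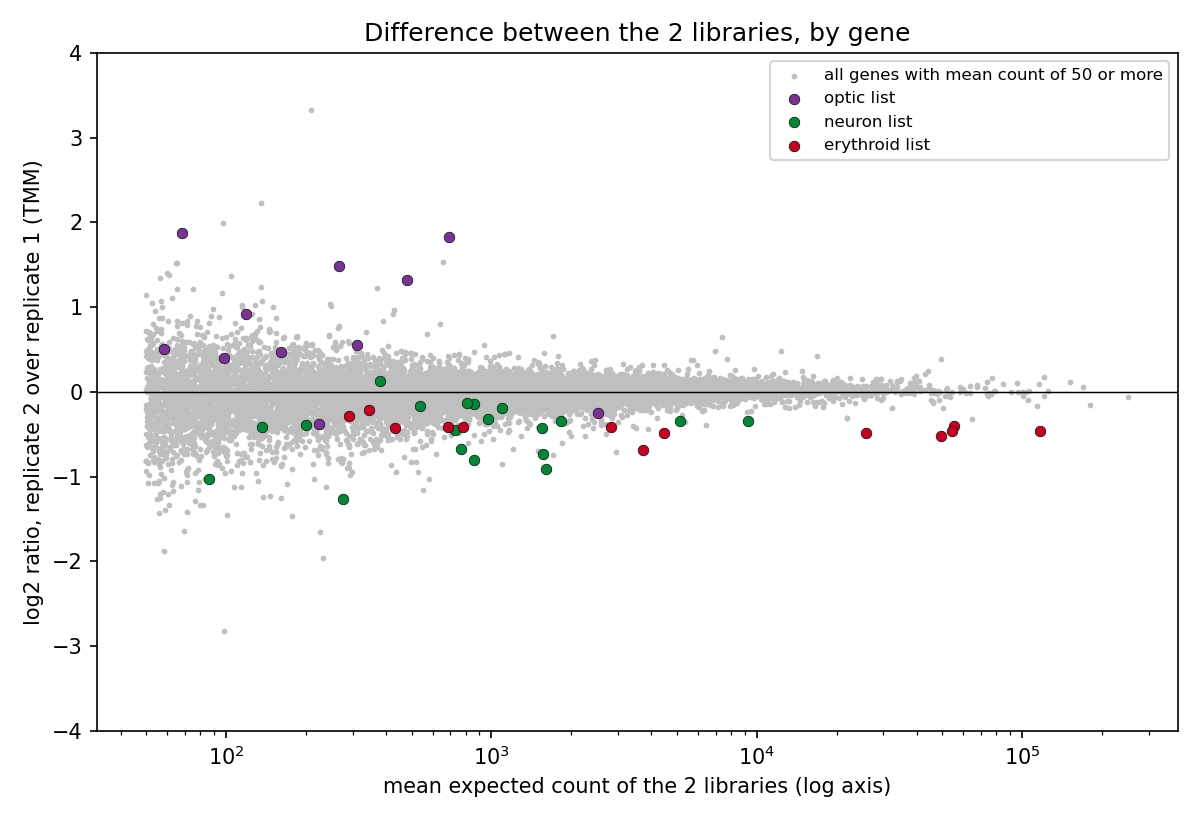
Log2 ratio of replicate 2 over replicate 1 for each gene, against the mean expected count of the 2 libraries on a log axis. Grey points are 13842 genes and coloured points the optic, neuron and erythroid lists. Optic genes lie mostly above 0, and neuron genes other than Syt1 and all 13 erythroid genes below it. The 5 genes beyond 4 on the log2 scale lie outside the axis.

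Against that background 20 genes stood apart between the pools, by over 5 spreads of genes of similar count and over 2-fold. Of the 11 higher in replicate 2, 4 belong to the optic list, namely Pmel, Tyr, Rax and Six6. Pmel (ENSMUSG00000025359.9, GRCm38 chromosome 10, 128704195 to 128720238, plus strand) had 327 counts in replicate 1 and 1054 in replicate 2 (3.54-fold higher, 95% interval 3.13 to 4.02), Trpm1, a melanocyte and retinal channel gene, 362 and 950 (2.88-fold, 2.55 to 3.26), and Tyr, the tyrosinase of pigment synthesis, 31 and 105 (3.68-fold, 2.47 to 5.75). Rax and Six6, transcription factors of the eye field, were 2.79-fold (2.30 to 3.39) and 2.5-fold (2.18 to 2.88) higher, and Aldh1a1, a retinoic acid synthesis enzyme (ENSMUSG00000053279.6, chromosome 19, 20492715 to 20643465, plus strand), was 10.0-fold higher (7.33 to 14.3), with 41 and 378 counts. Slc38a8 was 4.71-fold higher (3.48 to 6.56) and Tom1 2.34-fold higher (2.01 to 2.75).

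Of the 9 genes lower in replicate 2, Mapt belongs to the neuronal list and Olig3 to the diencephalic list, and the others to no list. Olig3 (ENSMUSG00000045591.5, chromosome 10, 19356533 to 19358604, plus strand) gave 375 and 87 counts (3.90-fold lower, 95% interval 3.10 to 5.01), Chl1 174 and 22 (7.06-fold lower, 4.60 to 11.8), Nxph4 350 and 101 (3.14-fold lower, 2.52 to 3.97) and Mapt, which encodes the axonal protein tau, 399 and 151 (2.40-fold lower, 1.99 to 2.92). Dusp8 was 2.04-fold lower (1.80 to 2.32) and Cntn2 2.23-fold lower (1.96 to 2.55). Of the 20 genes, 9 had expected counts that were not whole, which marks reads shared with other genes and makes them uncertain: besides Rax, Six6, Tom1 and Cntn2, these were 5 pseudogenes or zinc finger gene models. Rpl7a-ps11 and Gm5537 had no count in replicate 2 and were at least 93.6-fold and 51.9-fold lower against a floor of 3 counts, Gm14288 was 20.6-fold lower (13.7 to 35.5), Zfp965 was 20.2-fold higher (11.1 to 48.0), and Gm14440 had no count in replicate 1 and was at least 129.4-fold higher. In TPM the gaps of Gm14288 (5.49 and 1.78 in replicates 1 and 2) and Zfp965 (1.3 and 7.38) were smaller. The 11 genes with whole counts were 6 higher and 5 lower. With the spreads taken anew from genes with whole counts alone, 6 genes were called higher and 4 lower.

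As lists, optic genes were higher in replicate 2, while erythroid genes and neuronal genes were lower. The optic list had a median ratio of 0.92 on the log2 scale (1.89-fold higher), above the range of -0.23 to 0.14 that held 95% of 10000 random lists matched on mean count, with 11 of 13 members higher. Its median level differed the other way, at 2.70 TPM in replicate 1 and 2.10 in replicate 2, since the median level was that of Tbx2, which was lower in replicate 2 and was looked up after its value was seen. Early embryonic genes and p53 targets likewise had a lower median level in replicate 2 (22.8 and 21.9 TPM, 15.5 and 14.7 TPM) and a median ratio above 0. The erythroid median ratio was -0.43 (1.35-fold lower), with all 13 members lower, Hbb-y at 9046 TPM in replicate 1 and 6644 in replicate 2. The neuronal median ratio was -0.39 (1.31-fold lower), with 18 of 19 members lower and Syt1 the exception, and the Cajal-Retzius list was at -0.47 with 9 of 10 lower. Neurogenic commitment (-0.20) and pallial genes (-0.29) were lower and subpallial genes higher (0.17), and the cell cycle (0.01) and neuroepithelial (-0.01) lists lay inside their ranges. Of the 16 neuroepithelial members 6 were higher and 10 lower. Among the latter Fabp7, looked up after its value was seen, was 1.64-fold lower (95% interval 1.55 to 1.73). The pallial list shares Neurog1 (-0.46), Neurog2 (-0.47) and Eomes (-0.26) with the neurogenic list and Tbr1 (-0.98) with the Cajal-Retzius list. These shifts are therefore not separate. The other pallial members ran from Emx1 (-0.46) to Tfap2c (0.18).

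Of the 29 lists with at least 3 counted members, 15 lay outside their ranges, 5 above and 10 below. Chance would put 1.45 of the 29 outside if genes varied independently. Besides those named, early embryonic genes (0.13), p53 targets (0.11) and hypoxia genes (0.08) lay above, and the dorsal midline list (-0.16), the FGF and SHH list (-0.16), forebrain factors (-0.08), pericyte genes (-0.25) and structural RNAs (-0.31) below. Only 4 structural RNAs were counted, and the median is that of Rn7s1 and Rn7s2, copies of a single RNA; with Rn7s1 alone, chosen after the data were seen, the median of 3 was -0.306 (range -0.28 to 0.19). Forebrain factors, with 6 members higher and 6 lower, lay inside the range with TPM ratios (-0.0496) and with a mean count of 200 or more (0.0111), a minimum that also put pericyte genes (-0.0406) and p53 targets (0.0631) inside. With whole counts only, chosen after the data were seen, early embryonic (0.0848) and hypoxia genes (0.0909) lay inside. The members of a list can vary together, so a place outside the range describes these 2 pools alone. Inside their ranges were diencephalic (-0.08), midbrain (-0.14), synaptic (-0.27), glial (0.00), surface ectoderm (-0.08), placode and lens (0.04), mesenchyme (-0.03), endothelial (0.05), macrophage (-0.08), immediate early (0.09) and imprinted (0.04) genes. Of these, synaptic genes lay below their range under 5 of 7 other settings (-0.27 to -0.33), and imprinted genes above theirs with whole counts only (0.133). The sex-linked median (0.06) lay inside too, but that list joins genes of X inactivation, Xist (-0.31) and Tsix (-0.73), both lower beyond counting error and with shared reads, and Y-linked genes, of which Eif2s3y (0.41), Kdm5d (0.17) and Ddx3y (0.13) were higher beyond that error and Uty (-0.02) was within it. Counting error leaves out other variation between the libraries. With whole counts only, which leaves the 4 Y-linked genes, the sex-linked median was 0.152 (range -0.12 to 0.12). With a mean count of 200 or more it was 0.135 over 5 genes, above the range. Scaling to the spike-in total moved every ratio up by 0.17, which put forebrain factors (0.0885), the dorsal midline list (0.0047) and the FGF and SHH list (0.00759) above 0 and still below their ranges, which moved with them.

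**Figure D3:**
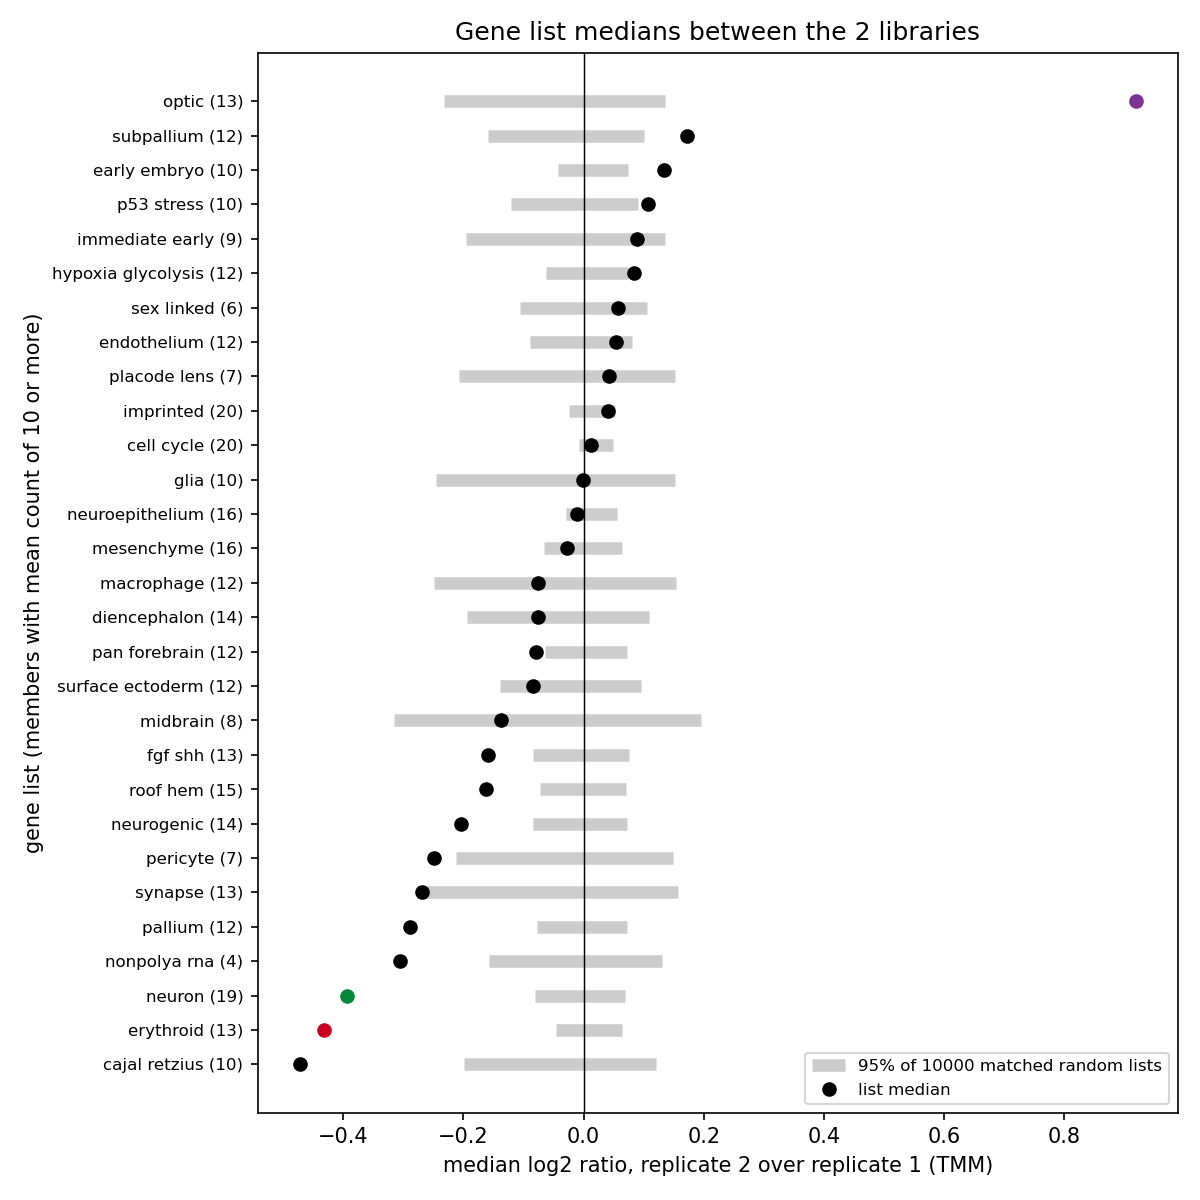
Median log2 ratio of replicate 2 over replicate 1 for 29 gene lists. Points are list medians (purple for optic, green for neuron, red for erythroid) and grey bars hold 95% of 10000 random lists matched on mean count; the optic list is farthest above 0, at 0.92, and the Cajal-Retzius list farthest below, at -0.47.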

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

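The tests for GC content and length, for melanoblasts, for diencephalic tissue and for neurons in every region were chosen after the results were seen; those on second lists of eye and erythroid genes were set before those lists were looked at, except for their members with whole counts.

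Entries that carry only a bare number as identifier, outside every comparison, held 56.51 expected counts in replicate 1 (in 9 entries) and 45 in replicate 2 (in 7), above the 3 counts that a count of 0 allows.

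Optic genes were higher in replicate 2 by a median of 0.92 on the log2 scale, and stayed at 0.948 (random range -0.22 to 0.14) after a length and GC trend was removed, which argues against that bias as the whole cause. The 8 optic transcription factors that melanoblasts are not known to express had a median of 0.979 (range -0.32 to 0.19). The set, with Otx2 (-0.26) in it, was chosen after the optic result was seen. The 6 of them with whole counts, without Rax and Six6, had a median of 0.712 (range -0.44 to 0.27). The rise was thus not confined to pigment genes, although some of these genes rest on few counts. All 8 are members of the optic list whose rise was to be explained. They therefore give no separate test of neural crest melanoblasts as its source. A second eye list, with 7 of 8 genes counted and none in another list, was higher by 0.423 (range -0.28 to 0.19), the value of Slc24a5, whose reads are shared, and by 0.472 (range -0.44 to 0.28) over 5 members with whole counts, the value of Cyp1b1, the only one of those 5 higher beyond counting error, while Tbx3 (9.52 and 7.88 TPM in replicates 1 and 2) was lower and Aldh1a3 (25.7 and 26.1) and Rab38 (6.43 and 6.72) differed by less than that error. More eye tissue in the replicate 2 pool is a hypothesis that may account for the pattern, with weak support from that list, which rests on 1 gene with whole counts higher beyond counting error. The single group gives no biological contrast, so no biological explanation was tested by the design.

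Neuronal genes were lower in replicate 2 by a median of -0.39, and stayed at -0.394 (range -0.08 to 0.07) with the length and GC trend removed, a trend of at most 0.115 for any gene, which argues against that bias. Less diencephalic tissue stays open, since the diencephalic median of -0.0766 lay neither at or above 0 nor below its range of -0.19 to 0.11. Fewer neurons in every region stays open too: 6 subpallial neuron genes, all held by other lists, stood at 0.0385, which is 0.432 above the neuronal list. That gap was less than the 0.508 width of their random range (-0.31 to 0.20), although more than that range's distance from 0 on either side. The 6 were Lhx6, Lhx8, Isl1, Dlx5, Dlx6 and Gad1, with 3 higher and 3 lower. Gad2 (-0.48) and Slc32a1 (-1.71, with 30 and 8 counts), synaptic list members left out of the 6, were lower beyond counting error. The value therefore depends on which genes were chosen. A difference in age between the pools was not tested.

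Erythroid genes were lower in replicate 2 by a median of -0.43, and stayed at -0.432 (range -0.05 to 0.07) with the length and GC trend removed, which argues against that bias. A second erythroid list, none of it in another list, was lower by -0.515 (range -0.20 to 0.13), with all 9 counted genes, each with whole counts, lower, among them Hemgn (16.7 and 11.8 TPM in replicates 1 and 2) and Rhd (12.3 and 9.06). Less blood in the replicate 2 pool is a hypothesis that may account for the pattern, while endothelial genes stood at 0.0535.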

How the results depend on the processing

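The settings with whole counts, rescaled TPM, a length and GC trend removed and a single 7SL copy were chosen after the data were seen, as were the tests that use them. Leaving out a library was not possible for ratios between libraries, and elsewhere it leaves the other library's value, which lies within 1 SD of the mean by construction and says nothing on stability. Genes detected (10355 to 17326 over 8 settings), list members detected (225 to 325), pairs led by the first gene (15 to 17), the coefficient of variation (0.062 to 0.0687) and the number of shifted lists (14 to 16) stayed within 1.5 times. Of 278 values of list levels 115 moved, as did 32 of 175 values of gene pairs, where 2 more turned in sign. A move was more than 1 SD, or over 1.5 times for the count over all lists or pairs, which each total includes. In the list shifts, 8 values of lists inside their ranges lay outside under another setting. Where a cause is not plain from the setting, the cause was not tested.

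Forebrain minus midbrain was 3.82 with a pseudocount of 1, 4.04 with posterior mean TPM and 3.78 with expressed members only. Forebrain minus HOX was 4.60 and 11.18 with pseudocounts of 1 and 0.01, 7.07 with posterior mean TPM, 7.22 with FPKM, 8.67 with CPM and 7.46 with means. Neuroepithelium minus neuron was 2.43 with means, and minus mesenchyme 1.87 with a pseudocount of 1 and 1.69 with means. Neuron minus glia was 2.5 with a pseudocount of 1 and 1.58 with expressed members. Neuron minus synapse was 2.34 with a pseudocount of 1, 2.78 with posterior mean TPM, 3.26 with CPM and 1.68 with expressed members. CPM, in which long genes weigh more, turned neurogenic minus neuron (-0.0697), Hk2 over Hk1 (-0.0961) and Nr2f1 over Nr2f2 (-0.50). Lists outside the random level range numbered 14, and 5 with expressed members only.

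Genes apart higher in replicate 2 numbered 6 with a mean count of 200, 7 at over 7 spreads and 6 with whole counts, which left 4 lower. Spike-in scaling, which adds 0.17 to every ratio, put forebrain factors at 0.0885, dorsal midline genes at 0.0047 and FGF and SHH genes at 0.00759. Forebrain factors were at -0.0496 with TPM ratios and 0.0111 with a mean count of 200, which put pericyte genes at -0.0406 and p53 targets at 0.0631, all inside the range. Whole counts put early embryonic genes at 0.0848 (4 members) and hypoxia genes at 0.0909 (6 members), inside the wider ranges of fewer members.

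The leading transcript's share was 74.5% at a gene TPM of 1, where 5 genes differed, and 79.7% with posterior mean TPM. As shares of expected counts, mitochondrial genes took 0.841%, ribosomal protein genes 2.56%, histones 0.182%, haemoglobins 0.739%, spike-ins 3.26% and 7SL RNA 0.105%, since short genes weigh less. Depth limited low genes most: the median spread of the ratio was 0.361 at mean counts of 50 to 200 and 0.0828 over 1000.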

Other observations

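Among genes outside the fixed lists, chosen after their values were seen, Aldh1a7, a neighbour of Aldh1a1 on chromosome 19 (20692953 to 20727562, minus strand), also stood higher in replicate 2, with 42 and 153 counts (3.97-fold, 95% interval 2.83 to 5.78). Both genes had whole counts in both libraries. Within the FGF and SHH list, Fgf17 (log2 -0.85), Etv4 (-0.68), Spry1 (-0.43), Etv5 (-0.42), Fgf15 (-0.38), Dusp6 (-0.23) and Spry2 (-0.16) were lower in replicate 2 beyond counting error, and Ptch1 (0.17) was higher. The counting intervals of Fgf8 (-0.13), Fgf18 (0.08), Shh (0.20), Gli1 (0.12) and Gli2 (0.05) included no difference. Scaling to the spike-in total adds 0.17 to each value, which takes Spry2 and Fgf8 above 0. Counting error leaves out other variation between the libraries. In spreads of genes of similar count, Fgf17 lay at -6.95 and Etv5 at -5.12. Dusp6 (-3.96), Spry1 (-3.92), Fgf15 (-3.90) and Etv4 (-3.80) were less far out, and Spry2 (-1.36) and Ptch1 (1.90) lay close to genes of similar count. No test between members of the list was made.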
